A study of Rattus norvegicus with 9 samples.

How the data were processed

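Messenger RNA of rat lung was sequenced in 9 stranded libraries made from total RNA, per the labels' protocols. RNA was extracted with a column kit and treated with DNase. The submitters' processing notes name FastQC, Trimmomatic 0.33, STAR 2.7.7a, Picard 2.21.7, featureCounts 1.6.5 of the Subread package, DESeq and DESeq2 1.30.0, and the rat build rn6 or Rnor_6.0, with no settings. Whether the counting used strand is not given in the sources used here, so overlapping and antisense genes are uncertain.

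The deposited table holds 1 value per gene and library for 16682 Ensembl genes with symbols, coordinates and biotypes, 15428 of them protein coding. The authors' values are a score in unit terms: reads divided by a library factor and rounded to whole numbers, as the deposited values and the submitters' processing notes show. Library totals differed little (12366823 to 12935509), and the median ratio of each library to the geometric mean over genes was 0.999 to 1.005. The pattern of whole numbers that occur among low values gave the value of 1 read in each library, 0.8016 to 1.232, hence about 10340682 to 15695304 reads over the listed genes. The search for that step, tested on simulated values, erred by at most 0.0006. Because rounding loses the exact reads, no count model was run. Genes with few reads are the least precise, and values near 0 are given per group without a bound.

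All 9 columns were matched to samples by their names. A design written before the data were examined called for a count model on reads and named the limma test used here for normalized values. Values were transformed to log2(value + 2). Genes with a value of at least 10 in at least 3 of the 9 libraries were kept, which left 15013 and removed 1669. limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all 9 libraries, so that the 3 comparisons share 1 estimate of the spread, with 6 residual and 3.13 prior degrees of freedom and a mean trend in the variance. Two-sided p-values of the moderated test were adjusted by the Benjamini-Hochberg method within each comparison, and genes under 0.05 were called. Means ± SD are of normalized reads over 3 libraries, and SE belongs to the log2 difference. No pair of libraries in a group agreed within sampling noise.

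Before the data were examined, 54 gene lists of cell types, pathways and complexes were written, with 1097 distinct genes. Of these, 985 were found in the file by symbol or through the RefSeq names of assembly GRCr8, and 948 were tested. Genes not found, Pecam1 among them, were not analysed here, nor were mitochondrially encoded genes. The entry for Y-linked Uty was matched by name to the X-linked Kdm6a and was not used. The 50 lists with at least 5 tested genes were tested against the other genes with camera, at a preset correlation of 0.01 and with an estimated one, and by fry. Camera p-values were adjusted over the 50 lists.

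Genes named were set by a rule written before the data were examined. In each comparison it took the 5 largest increases and 5 largest decreases among called genes with a mean of at least 2 CPM and groups that did not overlap. It then took the 3 called members of smallest adjusted p from the 8 lists of smallest camera p, 1 of every other list with at least 3 called members, and a panel of 13 genes. Some of the genes so chosen are left out of the text for length. Any other gene named is said to have been chosen after its values were seen. Of the panel, Pecam1 was not analysed here, and Il6 was below the filter.

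The gene test was tried on simulated data made from the real means and depths, with 200 genes changed, none of them of low mean. Genes were drawn independently at 1 dispersion of 0.015, without shifts of whole libraries, and list tests were not run. The rates below hold for that setting only. For the vehicle and control comparison the test recovered 76% of genes changed 1.5-fold and 100% of those changed 2-fold, with 11 false calls among 15029 tested genes. For SGC-CBP30 against vehicle these were 64% and 98%, with 9 false calls among 15013, and for SGC-CBP30 against control 70% and 100%, with 12 among 15035.

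Alternatives fixed beforehand were other scalings (median ratio, library total), no filter or a mean of at least 1 CPM, a minimum fold of 1.5, only the 6 libraries compared, the replicate number as a block, each library left out in turn, and other list tests. Added after the data were seen were quantile normalization, pseudocounts of 0.5 and 8, no mean trend, array weights, removal of the trend with genomic span by a lowess curve per library, Y-linked reads as a covariate, the mean of the cardiac markers as a covariate, and leaving out control 3 and vehicle lung 2. The covariate for Y-linked reads assumes the same shift in every group, although no CBP30 library had such reads. Groups without a drug effect were simulated 100 times to give the correlation that shared vehicle lungs produce. Genomic span is that of the gene in the file, from its start to its end. Transcript length and GC content were not used here.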

Results

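RNA was sequenced in 9 libraries of rat lung, 3 in each of 3 groups. Control rats were healthy and untreated. Those of the other groups had received monocrotaline, a plant alkaloid that injures lung vessels and is used to induce pulmonary arterial hypertension. They were then nebulized through the trachea with vehicle or with SGC-CBP30 at 275 nmol/kg in 4% DMSO and buffered saline. SGC-CBP30 inhibits the bromodomains of the histone acetyltransferases CBP and p300, the products of Crebbp and Ep300. The labels give no nebulization for the controls, so the vehicle and control lungs differ in both monocrotaline and nebulized vehicle. The deposited values are reads per gene scaled to a common library size and rounded, called normalized reads here. They summed to between 12366823 and 12935509 per library. The value of 1 read in each library placed the reads over the listed genes between about 10340682 (CBP30 lung 1) and 15695304 (control 3). Of 16682 genes listed, 15013 were tested with limma on log2(value + 2), and fold changes are on that scale. Coordinates are those of the file, on Rnor_6.0. The labels do not say that the libraries of a group came from separate animals, and p-values measure only the spread between these libraries.

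The first principal component held 40% of the variance and separated the vehicle lungs, at 26.8 to 61.9, from the CBP30 lungs, at -28.4 to -20.8. Control 3 lay at -45 on this axis, away from controls 1 and 2 at -4.6 and 3. The second component held 22.3% and separated the controls, at 27.7 to 34.9, from the CBP30 lungs, at -27.1 to -25.8. Libraries also differed in transcripts of the Y chromosome. Eif2s3y and Kdm5d, Y-linked genes named here after their values were seen, had 927 to 955 and 755 to 1034 normalized reads in controls 1 and 2 and in vehicle lungs 2 and 3. They had at most 5 in control 3, vehicle lung 1 and the 3 CBP30 lungs. Eif2s3, the X-linked partner of Eif2s3y and also picked afterwards, had 1751 to 1933 normalized reads in the 4 libraries with Y-linked reads and 2967 to 3173 in the 5 without. The labels give no sex. By these values the 4 libraries with Y-linked reads look male and the 5 without look female, so both sexes appear to be among the libraries. The values do not show whether a library bears a wrong label. Groups here are those of the labels. The drug comparisons therefore set 3 lungs without Y-linked reads against groups in which 1 of 3 lacked them.

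**Figure D1:**
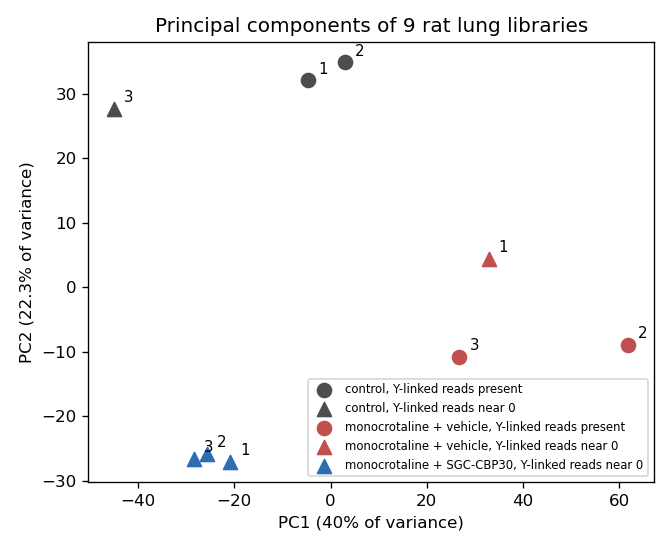
Principal components 1 (x axis, 40% of variance) and 2 (y axis, 22.3%) of log2 values, 1 point per lung, coloured by group, with circles for libraries with Y-linked reads and triangles for those near 0. Vehicle lungs lie at 26.8 to 61.9 on the first component and CBP30 lungs at -28.4 to -20.8.

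The comparison of vehicle with control lungs asks which transcripts differ in diseased lung. In vehicle lungs, all 16 cardiac muscle, 9 of 14 smooth muscle and 10 of 44 cell cycle genes were higher. Most mesothelial and erythroid and some ribosomal protein genes were lower. The macrophage and matrix glycoprotein gene Spp1, the fibrinolysis inhibitor gene Serpine1 and the complement gene C3 were also higher. In all, 2458 genes were higher and 2405 lower, of which 448 and 121 differed over 2-fold.

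All 16 tested cardiac muscle markers were higher in vehicle lungs, with a median log2 difference of 4.40. The list was written for the muscle of the pulmonary vein wall, but many of its genes mark heart muscle in general. Myh6, the cardiac alpha myosin heavy chain gene (ENSRNOG00000025757, chromosome 15, 33605654 to 33629699), had 3910 ± 4160 normalized reads in vehicle and 38.7 ± 63.5 in control lungs (SD, n = 3 each). Myl7, the atrial myosin light chain gene, had 2414, 3045 and 245 in vehicle lungs 1, 2 and 3, against 0, 136 and 1 in the controls. Mb, Csrp3 and Myh7 were the other 3 of the 5 largest increases, with control means of 12.7, 7.3 and 2.0, so their fitted folds depend on the pseudocount. Without control 3 and vehicle lung 2, the libraries that stood apart most, the adjusted p values of Myl7, Mb and Csrp3 were 0.0755, 0.0777 and 0.0748, and 9 other named genes of this comparison, among them Pln, F5, Mki67, Acta2, Slc6a7 and Mis18a, were not called either. The log2 differences kept their sign: Myl7 went from 7.02 to 5.54, Mis18a from -2.36 to -2.08, Mki67 from 0.93 to 0.91 and Pln from 2.43 to 1.61. Of 14 smooth muscle markers, 9 were higher and none lower, with a median of 0.80. Their mean deviation was 0.59 and 0.77 in vehicle lungs 1 and 2, which also held the most cardiac transcripts, and -0.03 in vehicle lung 3, against -0.65 to -0.15 in the controls. They included Myocd, the coactivator of smooth muscle genes, at 36.7 ± 4.9 against 14.0 ± 3.0. Synpo2 had 355 ± 117 against 143 ± 17.4, and Pln, which heart muscle also expresses, had 243 ± 164 against 38.0 ± 13.1. Acta2, the smooth muscle actin gene, was 1.69-fold higher (log2 0.76 ± 0.23 SE, adjusted p = 0.0347), a call that leaving out any of 5 single libraries ended.

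Of 44 cell cycle genes, 10 were higher and 1 lower in vehicle lungs, with a median of 0.50. Tyms, for thymidylate synthesis, was 1.97-fold higher, Kif23, a cytokinesis kinesin, 1.74-fold higher and Mki67 1.90-fold higher (adjusted p = 0.0271, a call that leaving out any of 4 single libraries ended), while the mitotic kinase gene Aurka was 1.43-fold lower. The mean deviation of the list from its 9-lung average was -0.78 in vehicle lung 1, within the range of the controls (-0.81 to -0.70), and 0.09 and 0.05 in vehicle lungs 2 and 3.

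Of 11 mesothelial markers, 7 were lower, with a median of -0.97. Their mean deviation was -0.40, -0.91 and -0.35 in vehicle lungs 1, 2 and 3 and -0.25 to 0.32 in the controls, lowest in the lung with the most cardiac transcripts. With the mean of the cardiac markers as a covariate, which was highest in the vehicle lungs, the median was -0.03. Gpm6a had 640 ± 210 against 1274 ± 252, Rspo1 392 ± 109 against 718 ± 113 and Nkain4 206 ± 43.7 against 405 ± 92.5. Of 15 erythroid genes, 10 were lower, with a median of -0.80. Ahsp, the alpha globin chaperone gene, had 41.0 ± 9.9 against 130 ± 36.9, and Hba-a2 was 1.86-fold lower, though near-identical globin genes share reads. Of 34 ribosomal protein genes, 15 were lower and none higher, with a median of -0.19, Rps28 by 1.52-fold and Rpl18 by 1.31-fold. Differences in this comparison rose with genomic span: of 4 equal groups of genes by span, the shortest had a median log2 of -0.138 and the longest of 0.217 (Spearman rho of fold change and span across genes 0.288). Removing that trend, a correction chosen after the data were seen, left the ribosomal list at an adjusted p of 0.25.

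Other differences lay in genes of lists that were not called as lists. Spp1 (ENSRNOG00000043451, chromosome 14, 6673686 to 6679901) had 528 ± 334 against 30.3 ± 23.6 (log2 4.02 ± 0.77 SE, adjusted p = 0.00566). Serpine1 was 3.84-fold and C3 2.28-fold higher, and the coagulation factor gene F5 2.92-fold higher, among 27 complement and coagulation genes of which 7 were higher and 2 lower. Il1a was 2.65-fold higher among 31 cytokine genes (5 higher, 2 lower). The macrophage genes Cd68 and Msr1 were 2.35-fold and 2.59-fold higher, the immediate early gene Nr4a3 8.19-fold and the chaperone gene Hsp90aa1 2.39-fold. Lower genes included the BMP target Id3 (2.12-fold), the endothelial transcription factor genes Sox18 (1.73-fold) and Sox17 (1.6-fold) and the apelin receptor gene Aplnr (1.82-fold). Tac1, the substance P precursor gene, had 10.7 ± 7.6 against 66.7 ± 17.8. Slc6a7, Sirpb3 and Mis18a were 6.09-fold, 5.29-fold and 5.14-fold lower, and 5S_rRNA, a multicopy gene whose reads cannot be placed with certainty, 5.57-fold lower.

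Of the drug's targets, Ep300 (ENSRNOG00000000190, chromosome 7, 122818975 to 122861296) had 399 ± 60.6 in vehicle and 136 ± 27.2 in control lungs (log2 1.54 ± 0.22 SE, adjusted p = 0.0025). Crebbp was 1.24-fold lower (adjusted p = 0.00508). Bmpr2, the main gene of heritable pulmonary arterial hypertension, was 1.59-fold higher (adjusted p = 0.00498). Edn1, Cdkn1a, Myc, Col1a1 and Sftpc did not pass the test (adjusted p = 0.832, 0.997, 0.993, 0.194 and 0.851).

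The limma test over 9 libraries, with Benjamini-Hochberg adjustment over 15013 genes, gave these calls. Groups did not overlap in 45.8% of all genes, where chance gives 10%. Without control 3 and vehicle lung 2 the counts were 1213 higher and 952 lower, and without vehicle lung 2 alone 1515 were lower. Of 50 lists tested against the other genes with camera at a preset correlation of 0.01, 6 were called: cardiac (adjusted p = 3.71e-06), smooth muscle (0.00412), cell cycle (0.000285), mesothelial (0.00484), erythroid (0.00015) and ribosomal (0.00015). With an estimated correlation all 6 had an adjusted p of 0.936. The smooth muscle list lost its call without vehicle lung 1 (adjusted p = 0.0571). Adjusted over the list alone, 16 cardiac, 10 smooth muscle, 9 cell cycle genes were higher and 9 mesothelial, 12 erythroid and 16 ribosomal genes lower.

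**Figure D2:**
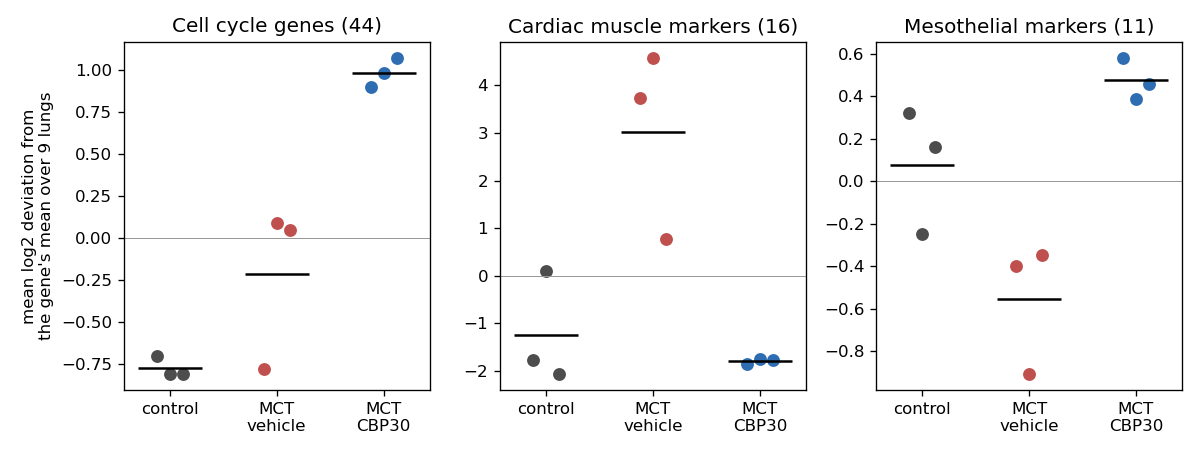
Mean log2 deviation of 44 cell cycle genes, 16 cardiac muscle markers and 11 mesothelial markers from each gene's mean over 9 lungs (y axes), 1 point per lung by group (x axes), with a line at the group mean. Cell cycle means are 0.90 to 1.07 in CBP30 lungs and -0.81 to -0.70 in controls, and the cardiac mean is 0.77 to 4.57 in vehicle lungs.

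The comparison of SGC-CBP30 with vehicle asks what the inhibitor changed in monocrotaline-treated lung. In CBP30 lungs nearly the whole cell cycle list was higher, with 10 of 11 mesothelial, 12 of 32 matrix, 9 of 21 macrophage and 11 of 23 unfolded protein response genes. Cardiac muscle genes, 10 of 17 B cell genes, Ep300 and Bmpr2 were lower. In all, 2001 genes were higher and 1785 lower, 296 and 292 of them over 2-fold.

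Of 44 cell cycle genes, 39 were higher in CBP30 than in vehicle lungs and none lower, with a median log2 of 1.27. Pcna, the DNA polymerase clamp gene (ENSRNOG00000021264, chromosome 3, 124880698 to 124884570), had 1906 ± 26.1 against 1185 ± 115 normalized reads (log2 0.69 ± 0.08 SE, adjusted p = 0.00416). Ccne1, the G1/S cyclin gene, had 91.7 ± 6.1 against 23.7 ± 7.2, and Mcm4, of the replicative helicase, 776 ± 32.8 against 452 ± 57.6. Mki67 (chromosome 1, 207993895 to 208020454) had 1094 ± 68.3 against 444 ± 173, and Foxm1, a mitotic transcription factor gene, was 2.28-fold higher. Cenpw, a centromere gene, and Pimreg, which acts in mitosis, were among the 5 largest increases, at 4.97-fold and 6.16-fold. With Y-linked reads as a covariate 40 members were higher, with a median of 1.66. Set against vehicle lungs 1, 2 and 3 singly, the median was 2.08, 0.92 and 0.94, and 43 of 44 members were higher in the CBP30 mean each time.

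The other largest increases were Fcrl2, at 114 ± 41.7 against 7.3 ± 1.2, the neuronal tubulin-binding gene Stmn2, at 515 ± 118 against 77.3 ± 33.2, and the epidermal growth factor receptor ligand gene Areg, at 240 ± 142 against 37.0 ± 7.8. Of 32 collagen and matrix genes, 12 were higher and none lower, with a median of 0.53. Tnc, for tenascin C (chromosome 5, 79789671 to 79874671), had 1328 ± 176 against 303 ± 106, Loxl1, a matrix cross-linking enzyme gene, was 2.02-fold higher and Mfap5 1.76-fold. Col1a1 had 4033 ± 756 against 1518 ± 492 (log2 1.44 ± 0.29 SE, adjusted p = 0.0105, and 1.34 ± 0.37 and 0.0556 with Y-linked reads as a covariate). Of 11 mesothelial markers, 10 were higher, with a median of 1.24, Gpm6a by 2.60-fold and Nkain4 by 2.12-fold. With the mean of the cardiac markers as a covariate the mesothelial median was 0.20 and the matrix median 0.21, and neither list was called (adjusted p = 0.226 and 0.211).

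Of 21 monocyte and interstitial macrophage markers, 9 were higher and 1 lower, among them Aif1 (1.52-fold), F13a1 (1.79-fold) and the scavenger receptor gene Cd163, at 104 ± 45.7 against 35.7 ± 1.2. Of 31 cytokine and chemokine genes, 8 were higher and 1 lower, with Ccl12 2.73-fold higher. Of 23 unfolded protein response genes, 11 were higher and none lower: Ddit3, a stress transcription factor gene, by 1.44-fold, Chac1 by 2.75-fold and Manf by 1.49-fold. With the cardiac covariate the median of this list went from 0.24 to 0.09 and its call ended (adjusted p = 0.169), while the macrophage list kept its call (median 0.48, adjusted p = 0.0111). Of 34 ribosomal protein genes, 8 were higher, with a median of 0.19. With the span trend removed the ribosomal and cytokine lists had an adjusted p of 0.172 and 0.0947.

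All 16 cardiac markers were lower than in vehicle lungs, with a median of -5.10. Myl7 had 2.0 ± 1.7 in CBP30 lungs against 1901 ± 1470, Myh6 5.7 ± 2.9 against 3910 ± 4160 and Actn2 0.3 ± 0.6 against 343 ± 362, so the fitted folds depend on the pseudocount. The SD within vehicle lungs was above the mean for Myh6 and Actn2 and below it for Myl7. Of 17 B cell markers, 10 were lower, with a median of -1.19. Their mean deviation was 0.30, 1.21 and -0.23 in vehicle lungs 1, 2 and 3 and -0.84, -0.21 and -0.83 in CBP30 lungs 1, 2 and 3, so that vehicle lung 3 lay beside CBP30 lung 2. The highest, vehicle lung 2, also held the most cardiac transcripts, and with the mean of the cardiac markers as a covariate the median was 0.07. Cd79b had 220 ± 37.0 against 531 ± 234, Ms4a1, the gene of CD20, 44.7 ± 28.9 against 165 ± 101 and Cd79a 126 ± 27.2 against 283 ± 122. Leaving out any of 4 single libraries ended the Cd79a call, any of 3 the Ms4a1 call and 1 the Cd79b call. Without control 3 and vehicle lung 2 the Ms4a1 and Cd79a calls ended (adjusted p = 0.0522 and 0.0599). With Y-linked reads as a covariate all 3 calls ended (adjusted p = 0.0905, 0.101 and 0.0927). The log2 of Cd79b went from -1.19 ± 0.27 to -0.99 ± 0.33 (SE), of Ms4a1 from -1.85 ± 0.46 to -1.65 ± 0.57 and of Cd79a from -1.08 ± 0.29 to -1.09 ± 0.37, while the list kept its call at the preset correlation (median -1.07, adjusted p = 7e-04). Without that covariate and with an estimated correlation the list had an adjusted p of 0.871. Of 15 ciliated cell markers 2 were lower, with a median of -1.02, and of 25 fatty acid oxidation genes 6 were lower and 1 higher. Ppargc1a, a coactivator of mitochondrial genes, was 2.62-fold lower. Neither the ciliated nor the fatty acid list kept its call with Y-linked reads as a covariate (adjusted p = 0.137 and 0.131), and the fatty acid list also lost it without CBP30 lung 2 (0.0512).

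Ep300 had 156 ± 45.6 in CBP30 and 399 ± 60.6 in vehicle lungs (log2 -1.37 ± 0.22 SE, adjusted p = 0.00631). Crebbp did not pass the test (log2 0.09 ± 0.06, adjusted p = 0.283). With the span trend removed it was called higher, at a log2 of 0.31 (adjusted p = 0.0207), so its size depends on that correction. Bmpr2 (chromosome 9, 66568074 to 66676494) was 1.75-fold lower (adjusted p = 0.00589). The vascular receptor phosphatase gene Ptprb was 2.15-fold lower, the phosphodiesterase gene Pde3a 2.04-fold, the protease inhibitor gene Serpina1 4.34-fold and the alveolar lipid transporter gene Abca3 1.45-fold (log2 -0.53 ± 0.11 SE, and -0.50 ± 0.14 with an adjusted p of 0.0561 with Y-linked reads as a covariate). Cdkn1a, the p21 gene, had 3197 ± 602 against 1656 ± 310 (adjusted p = 0.00942). Myc was 1.27-fold higher (adjusted p = 0.0497), and leaving out any of 8 single libraries ended that call. Spp1, Edn1, Acta2 and Sftpc did not pass the test (adjusted p = 0.241, 0.543, 0.23 and 0.916).

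Groups did not overlap in 45.4% of genes, where chance gives 10%. With Y-linked reads as a covariate, a fit chosen after the data were seen, 861 genes were higher and 576 lower. Of the 3786 called genes, 1273 were called in both fits with the same sign. The other 2513 also kept their sign, with a median size of 0.42 before and 0.35 after (log2) and a median SE of 0.107 and 0.123. With the span trend removed 1182 were lower. Counts fell to 817 higher without CBP30 lung 2 and 679 lower without CBP30 lung 3. They were 880 higher without CBP30 lung 3, 682 lower without CBP30 lung 2, 1158 and 1015 without vehicle lung 2, and 1027 lower without vehicle lung 3. With the mean of the cardiac markers as a covariate, limma called no gene in this comparison or in vehicle against control, with 2052 and 3257 genes at an unadjusted p under 0.05. Of the called genes 97.4% and 99% kept their sign, and the median SE rose from 0.129 to 0.264 and 0.241. The log2 differences changed too, correlating at 0.482 and 0.593 with those of the fit without the covariate. The cell cycle median for CBP30 against vehicle was 0.96 (list adjusted p = 2.09e-10). Camera called 11 lists: cell cycle (adjusted p = 3.77e-17), mesothelial (5.08e-05), ribosomal (4.43e-05), matrix (0.000108), unfolded protein response (0.00392), macrophage (0.00511) and cytokine (0.0152) genes higher, and cardiac (2.2e-08), B cell (0.000301), ciliated (0.00742) and fatty acid oxidation (0.0186) genes lower. With an estimated correlation the adjusted p of each was 0.72 or 0.871. Adjusted over the list alone, 41 cell cycle, 10 mesothelial, 11 ribosomal, 16 matrix, 11 unfolded protein response, 9 macrophage and 8 cytokine genes were higher, and 16 cardiac, 12 B cell, 0 ciliated and 6 fatty acid oxidation genes lower.

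Many genes that differed between vehicle and control lungs differed the other way between CBP30 and vehicle lungs. The 4863 genes called between vehicle and control lungs are named disease genes here. That name does not separate monocrotaline from nebulized vehicle or from the tissue sampled, and moved back means only a call of opposite sign. Of the 4863 disease genes, 2287 (47%) were called in the opposite direction with SGC-CBP30, 78 in the same direction and 2498 not at all. Of the 2287, 1223 had been higher in vehicle lungs, including Ep300, Bmpr2, Skil, a TGF-beta feedback gene, and the acetyltransferase gene Kat6a. The 1064 that had been lower included Ahsp, Gpm6a and Mfap5. All 16 cardiac markers and the 7 called mesothelial markers moved back, while 9 of the 11 called cell cycle genes moved further the same way and 1 moved back. Of the disease genes, 740 were still called against control with the same sign and 20 with the opposite sign.

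Both comparisons use the same vehicle lungs, which gives an opposite trend without any drug effect. The fold changes of the 15013 genes correlated at r = -0.634. Simulated drug groups without an effect gave a mean r of -0.207 with independent noise and of -0.217 with whole-library residuals, the latter ranging from -0.75 to 0.527 over 50 draws. The observed r lies within that last range, so whole-library shifts without a drug effect can give an r of this size. The covariance was -0.201, against means of -0.0317 and -0.0415 over the simulated draws, whose range is not given. Independent lists of these sizes would share 612.8 opposite and 613.6 same-direction calls. With the vehicle lungs split so that none served both comparisons, 1 lung going to either comparison and 2 to the other, r was -0.503 to -0.312 over 6 arrangements. With Y-linked reads as a covariate 770 genes moved back and r was -0.50. The count was 946 without CBP30 lung 2, 977 without CBP30 lung 3, 1135 without vehicle lung 2 and 1251 without vehicle lung 3. Without control 3 and vehicle lung 2 it was 1001, and r was -0.43. With the mean of the cardiac markers as a covariate no gene was called in either comparison, so none moved back. The median SE there rose from 0.129 to 0.241 and 0.264. Fold changes also followed genomic span in opposite directions, with a Spearman rho of 0.288 and -0.29, against 0.039 for CBP30 against control. A trait that the vehicle lungs share would also give opposite signs.

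**Figure D3:**
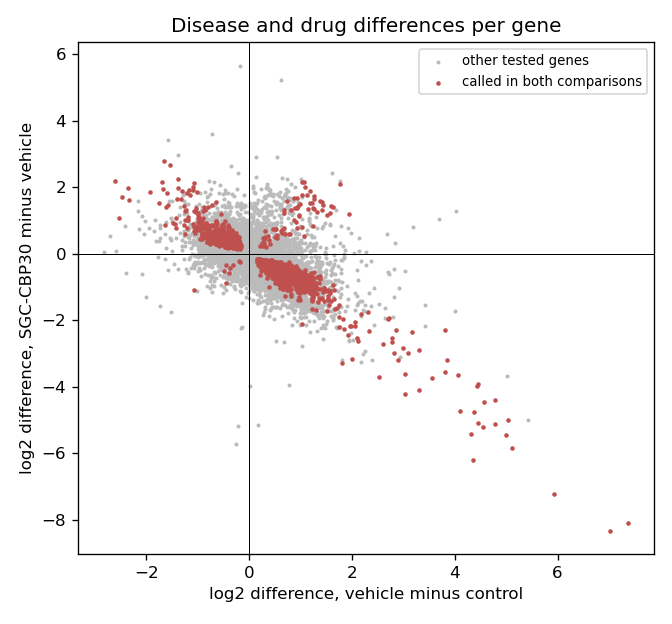
Log2 difference of vehicle minus control lungs (x axis) and of CBP30 minus vehicle lungs (y axis) for 15013 genes, with genes called in both in red. Of the red points 2287 lie in the opposite-sign quadrants and 78 in the same-sign quadrants, and the shared vehicle lungs add to the downward slope.

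The comparison of CBP30 with control lungs asks how far treated diseased lung differed from healthy lung. Proliferation genes and macrophage genes such as Spp1, Trem2 and Gpnmb were higher in CBP30 lungs, as were some p53 response, heat shock and unfolded protein response genes. Of natural killer cell, B cell, erythroid and endothelial genes, 4 of 13, 1 of 17, 4 of 15 and 3 of 18 were lower. In all, 923 genes were higher and 550 lower, 335 and 53 of them over 2-fold.

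Of 44 cell cycle genes, 40 were higher and none lower, with a median log2 of 2.0. Mki67 had 1094 ± 68.3 against 220 ± 31.5 (log2 2.31 ± 0.27 SE, adjusted p = 0.0023), and Foxm1 371 ± 28.5 against 120 ± 6.1. Nuf2, of the kinetochore, was 4.98-fold higher. Ckap2, a spindle gene, was among the 5 largest increases at 558 ± 94.7 against 37.0 ± 7.6. Of 21 macrophage markers 11 were higher, with a median of 0.59. Spp1 had 1297 ± 793 against 30.3 ± 23.6, the lipid receptor gene Trem2 1181 ± 100 against 218 ± 35.5 and Gpnmb 15230 ± 1690 against 5331 ± 1550. Mmp12, macrophage elastase, was 9.60-fold higher and the scavenger receptor gene Marco had 58.7 ± 40.5 against 1.3 ± 1.5, a call lost with Y-linked reads as a covariate (log2 3.96 ± 0.94 before, 2.90 ± 1.03 after, adjusted p = 0.104) and by leaving out any of 5 single libraries. Vxn, a gene of neuronal differentiation, had 196 ± 49.4 against 5.3 ± 1.5.

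Of 32 matrix genes 7 were higher, Thbs2 by 4.19-fold and Thbs1 by 2.56-fold, and of 20 TGF-beta response genes 6, with Serpine1 (chromosome 12, 22641104 to 22651482) at 1442 ± 296 against 165 ± 51.0. Of 26 p53 response genes 9 were higher and 2 lower, with Ccng1 2.03-fold higher and Cdkn1a 1.93-fold, a call lost without CBP30 lung 2 or 3. Of 16 heat shock genes 7 were higher, Dnaja1 by 1.44-fold, and of 23 unfolded protein response genes 7, Asns, for asparagine synthesis, by 1.47-fold. Of 31 cytokine genes 9 were higher, Il1a by 2.15-fold.

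Of 13 natural killer and cytotoxic cell markers 4 were lower, with a median of -0.79. Tbx21, which directs their maturation, was 2.3-fold lower, and Klrd1 had 155 ± 19.9 against 330 ± 31.5. Of 17 B cell markers 1 was lower, with a median of -0.81. Of 18 endothelial markers 3 were lower: Sox18 by 1.69-fold, Vwf by 1.35-fold and Tie1 by 1.32-fold, and the Vwf call ended with Y-linked reads as a covariate (log2 -0.44 ± 0.09 before, -0.37 ± 0.11 after, adjusted p = 0.0649). Leaving out any of 4 single libraries ended the Vwf call, and any of 6 the Tie1 call. Of 26 BMP signalling genes 3 were lower, Hey1, a Notch and BMP target, by 1.74-fold, and of 15 erythroid genes 4. Aplnr was 2.07-fold, Sox17 1.62-fold, Tac1 5.76-fold and Sirpb3 7.97-fold lower. The leukotriene synthase gene Ltc4s was 3.66-fold and Serpinb10 4.46-fold lower. Ep300 and Bmpr2 did not pass the test (adjusted p = 0.661 and 0.501), nor did Col1a1 (0.0779, and 0.00771 without control 3 and vehicle lung 2). Crebbp was 1.17-fold lower (adjusted p = 0.0419), a call ended by leaving out any of 7 single libraries. The Crebbp call also ended with the span trend removed (adjusted p = 0.0729) and with Y-linked reads as a covariate (0.0719). Without control 3 and vehicle lung 2 it had an adjusted p of 0.0906.

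Groups did not overlap in 34.3% of genes, where chance gives 10%. Counts fell to 496 higher and 197 lower without control 1, and to 548 and 171 without control 2. Without CBP30 lungs 1, 2 and 3 in turn they were 498 and 187, 478 and 178, and 468 and 202. They rose to 1612 and 1159 with array weights, and 891 were lower without control 3 and vehicle lung 2. Camera called 13 lists higher and 7 lower at the preset correlation. With an estimated correlation no list passed, with the lowest adjusted p at 0.261, for 6 lists including cell cycle, macrophage and p53 genes. Those not yet described with their genes were complement and coagulation (adjusted p = 0.00201, 7 higher and 2 lower of 27), interferon response (0.00204, 2 of 31 higher), basement membrane (0.0061, 2 of 16 higher), NF-kappaB target (0.0429, 1 of 23 higher) and alveolar type 1 genes (0.0342, 1 of 15 higher). The acetyltransferase, bromodomain and deacetylase list (0.00737, 3 of 29 lower) and the fatty acid oxidation list (0.00907, 2 of 25 lower) were called lower. The adjusted p was 1.85e-33 for cell cycle, 4.26e-07 for unfolded protein response, 2.34e-06 for macrophage, 0.000155 for matrix and for heat shock, 0.000836 for cytokine, 0.00134 for p53 and 0.00175 for TGF-beta genes. For the lists that were lower it was 0.000133 for natural killer, 0.000155 for B cell, 0.00024 for erythroid, 0.000378 for endothelial and 0.0257 for BMP genes. Adjusted over the list alone, 42 cell cycle, 12 unfolded protein response, 12 macrophage, 10 matrix, 9 heat shock, 10 cytokine, 12 p53 and 11 TGF-beta genes were higher, and 7 natural killer, 6 B cell, 9 erythroid, 7 endothelial and 5 BMP genes lower. With Y-linked reads as a covariate 16 of the 20 lists kept their call, and alveolar type 1 (adjusted p = 0.0566), basement membrane (0.0663), NF-kappaB target (0.151) and fatty acid oxidation genes (0.258) did not. The alveolar type 1, NF-kappaB, fatty acid oxidation and BMP lists also lost it without 4, 3, 2 and 1 of the single libraries.

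**Figure D4:**
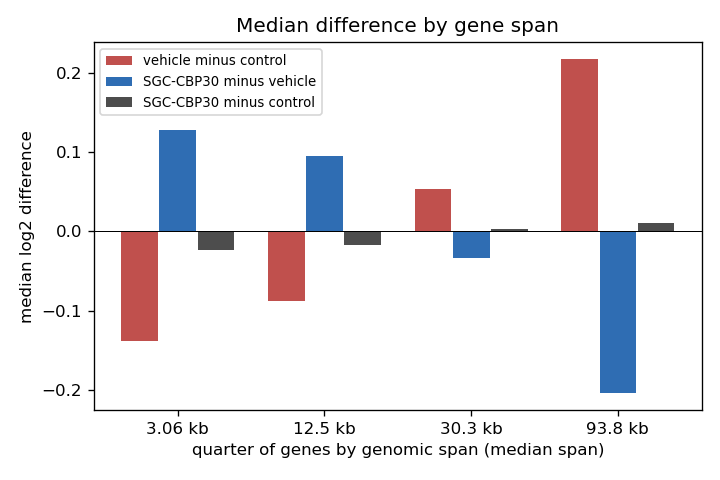
Median log2 difference (y axis) of 4 equal groups of genes ordered by genomic span in the file, labelled by median span (x axis), for each comparison. In vehicle minus control the medians run from -0.138 at 3.06 kb to 0.217 at 93.8 kb, and in CBP30 minus vehicle from 0.128 to -0.204.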

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

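The tests named as added in the processing were chosen after the data were seen. Median-ratio, library-total and quantile scaling, no filter, a mean of at least 1 CPM, pseudocounts of 0.5 and 8 and the fits of 6 libraries left every count of genes and lists that they gave within 1.5 times its value. The fits of 6 libraries gave no count of genes moved back. DESeq2, edgeR and limma-voom, planned for reads, were not run because the values are not counts. Depth limits genes of few reads, where rounding and the pseudocount weigh most.

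A fold of at least 1.5 left 1290 genes higher and 535 lower for vehicle against control, 634 and 807 for SGC-CBP30 against vehicle, and 514 and 161 for SGC-CBP30 against control, fewer by construction. With array weights 1612 and 1159 genes were called in the last comparison, and without the mean trend 337 were lower. With the span trend removed 1182 genes were lower with SGC-CBP30 than with vehicle. With Y-linked reads as a covariate 861 were higher and 576 lower there, 770 disease genes moved back and r was -0.5005. Without control 3 and vehicle lung 2, the counts were 1213 and 952 for vehicle against control, 891 lower for SGC-CBP30 against control, 1001 moved back and r of -0.4304. With vehicle lungs split, r averaged -0.4232. The cause of these shifts was not tested.

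With the mean of the cardiac markers as a covariate, limma called 0 genes in the first 2 comparisons (3257 and 2052 at unadjusted p under 0.05) and 0 moved back. The median SE rose from 0.129 to 0.241 and 0.264, and 99% and 97.4% of called genes kept their sign. The mean deviation of the cardiac markers was 3.73, 4.57 and 0.77 in vehicle lungs 1, 2 and 3 and at most 0.11 in the controls. This covariate thus goes largely, but not wholly, with the vehicle group. The log2 differences changed too, correlating at 0.593 and 0.482 with those of the fit without the covariate. Lists called with the covariate were 8 and 12. There the log2 of Mb (vehicle against control) was -0.158, and with SGC-CBP30 against vehicle Cd79a was at 0.06098 and Gpc3 at -0.08899, each with the opposite sign. Lists whose direction by camera turned had adjusted p of 0.9152 (cardiac) and 0.7327 (mesothelial) for vehicle against control. For SGC-CBP30 against vehicle they had 0.3093 (ciliated), 0.8519 (cardiac), 0.5289 (B cell) and 0.8777 (fatty acid oxidation). The median log2 kept its sign for the mesothelial list in the first comparison (-0.03) and the cardiac list in the second (-0.08).

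With an estimated correlation 0 lists were called in each comparison. Fry called 1, 10 and 11 lists, of which 0, 7 and 10 were among camera's 6, 11 and 20. Its only list for vehicle against control was TGF-beta response genes (adjusted p = 0.0406), and camera's 6 there had 0.0571 to 0.216 by fry.

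Replicate numbers did not pair the lungs: same-numbered deviations correlated at -0.167 to 0.324, and 4 of 9 were best with their own number. With the replicate block, 2261 and 2129, 1730 and 1659, and 697 and 340 genes were called higher and lower, and 1871 moved back.

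Leaving out each library in turn gave 1695 to 2509 higher and 1515 to 2439 lower for vehicle against control, 817 to 2197 and 679 to 2332 for SGC-CBP30 against vehicle, and 468 to 1064 and 171 to 711 for SGC-CBP30 against control. Lists called ranged over 6 to 10, 11 to 17 and 20 to 24, genes moved back over 946 to 2429 and r over -0.6884 to -0.5096. Over all alternatives the named genes gave 4547 comparisons, of which 4213 kept direction and side of the threshold, 327 lost the call, 4 gained it and 3 changed sign. The called lists gave 962, of which 870 kept both, 86 lost the call and 6 turned in the direction given by camera.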

Other observations

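Tests of the cardiac, span and cell cycle patterns were chosen after the result was seen, except those on cartilage genes and on a class of short genes, as were the counts of lists over other splits of the libraries.

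Genes of histone acetylation moved in both directions. Of 29 acetyltransferase, bromodomain and deacetylase genes, 6 were higher and 8 lower in vehicle than in control lungs, and 2 were higher and 9 lower in CBP30 than in vehicle lungs. Of the 14 called in the first comparison, 8 were called the other way in the second and none further the same way. Among all 4863 disease genes these were 2287 (47%) and 78, so the 8 do not set this list apart. Kat6a, an acetyltransferase gene, had 2118 ± 137 normalized reads in vehicle, 1361 ± 136 in CBP30 and 1328 ± 29.7 in control lungs. Hdac5, a deacetylase gene, was 1.33-fold lower in CBP30 than in control lungs, a call that leaving out any of 3 single libraries ended. The list was not called in the first or the second comparison (adjusted p = 0.718 and 0.189).

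Of 26 p53 response genes, 11 were higher and 4 lower in CBP30 than in vehicle lungs, although the list was not called (adjusted p = 0.0564). Phlda3 was 1.63-fold and Cdkn1a 1.93-fold higher. The members called lower were named after their values were seen: Rrm2b, a nucleotide reductase gene, Xpc, of DNA repair, Sesn1 and Tp53inp1. Alveolar type 2 markers did not differ as a list in any comparison (adjusted p = 0.548, 0.189 and 0.54), and the surfactant gene Sftpc had 52810 ± 2010, 51840 ± 7340 and 50830 ± 4630 normalized reads in control, vehicle and CBP30 lungs.

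Cardiac muscle genes were high in vehicle lungs 1 and 2, and so were the airway secretory genes Clca1 (1677 and 1518 normalized reads) and Bpifa1 (1283 and 7422), picked after their values were seen, against at most 22 and 50 in the other 7 libraries. A fragment of heart ventricle is argued against, since the ventricular light chain gene Myl2 reached 6 where atrial Myl7 reached 3045. These values bear on ventricle only, and a fragment of atrium was not tested. The span trend is also argued against, since the median without it was 4.45. More tissue from near the hilum, with pulmonary vein muscle and large airway, may be the source, but the test could not decide. Only 4 of 12 cartilage genes were tested, mostly at low values. Their mean deviation was 0.31 in vehicle lung 1 and 0.63 in control 1, the highest other library, a gap of -0.32 (SD over genes 1.53). By the rule written beforehand this went against the hilum as the source, but the gap lay within that spread. Of these genes Chad, picked after its values were seen, goes with that source, at 61 and 139 normalized reads in vehicle lungs 1 and 2 and at most 15 in the other 7 libraries, while Snorc, Comp and Col11a1, also named afterwards, were not highest there. Growth of pulmonary vein muscle in disease stays open and untested.

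Long genes were higher and short genes lower in vehicle than in control lungs, and the reverse held for SGC-CBP30 against vehicle. A class of 300 short ribosomal, mitochondrial and proteasome genes does not account for it, since rho was 0.279 without them and 0.288 with them. Per library, the rho of deviation and span was 0.23 to 0.309 in vehicle lungs and -0.184 to -0.131 in controls. It was -0.006, -0.215 and -0.217 in CBP30 lungs 1, 2 and 3. These lungs also had monocrotaline, so the trend went with the vehicle group and not with monocrotaline alone. RNA quality or preparation that differed between groups cannot be told apart from the treatments. Every vehicle library lay above every control, by at least 0.361 in rho, and the labels give no preparation batch. With the trend removed, 3454 of 4863 disease calls and 2359 of 3786 drug calls stood with the same sign.

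Cell cycle genes were higher in CBP30 than in vehicle lungs (39 of 44 members called). Of the technical explanations, 3 are argued against as the whole cause. The median was 1.34 without the span trend and 1.66 with Y-linked reads as a covariate. Dilution by cardiac and airway tissue that acts on all lung markers needs them to rise alike. The median of alveolar type 2 markers was -0.10 (SD over members 0.22) and that of endothelial markers -0.15 (0.36). Mesothelial markers did rise, with 10 of 11 higher and a median of 1.24, so only such an even dilution is argued against. With the mean of the cardiac markers as a covariate the mesothelial median was 0.2 and the cell cycle median 0.96, with no cell cycle member called. Vehicle lung 1, which lacked Y-linked reads as the CBP30 lungs did, lay furthest below them (2.08), and control 3 without such reads was at -0.81 beside controls 1 and 2 at -0.70 and -0.81. An effect of the drug and a difference in disease between the animals stay open and untested.

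In the drug comparison 861 genes were higher and 576 lower with Y-linked reads as a covariate, against 2001 and 1785 without it. All 2513 genes that lost their call kept their sign. Their median size went from 0.42 to 0.35 (log2; median ratio 0.82) and their median SE from 0.107 to 0.123, so smaller differences and a larger error both took part, and the loss of calls alone does not show an effect of sex. Of the 62 named genes called there, 45 kept their call and 17 lost it, among them Gpc3 at 0.93 ± 0.20 before and 0.93 ± 0.25 after (SE), and Ahrr at 1.99 ± 0.45 and 1.27 ± 0.37. No CBP30 library had Y-linked reads, so a drug effect that depends on sex cannot be estimated here.

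The 6 libraries of each comparison have 10 splits into 3 and 3, too few for a share under 0.05. In each comparison 1 split, the real one, gave as many called genes: 4863, 3786 and 1473 genes against at most 0, 2 and 0 in the others. List counts behaved otherwise. As many lists as the real 6, 11 and 20 were called in 10, 8 and 5 of the 10 splits, with up to 22, 26 and 29 in the others. The number of lists called therefore does not set the real groups apart. Each other split mixes lungs of both groups and keeps part of their difference, so the cause of these counts was not tested. The B cell median for CBP30 against vehicle was 1.19 in size in the real split and at most 1.13 in the others. The cell cycle median for that comparison was 1.27 in the real split and at most 0.73 in size in the others, but for vehicle against control 4 of 10 splits gave a median as large as 0.50. For genes moved back, 1 of 100 assignments of the 9 libraries, the real one, gave as many as 2287, and the highest other gave 137. Assignments that mix the groups put the group differences into the spread and so call few genes. The vehicle lungs also serve both comparisons, so this count cannot tell a drug effect from a trait that the vehicle lungs share.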
